A study of Mus musculus with 14 samples.

How the data were processed

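Experiment B comprised 10 libraries of total RNA extracted with RNeasy, 2 from each of 5 media, and experiment A comprised 4 single libraries of total RNA extracted with Trizol from cells described as positive for both reporters. The descriptions name no sorting step. Day 0 cells of experiment A were titled untreated, and the protocol kept them in serum and LIF with vitamin C at 100 µM. L-proline was given there at 1 mM, and F/A held activin A at 20 ng/ml with bFGF. The protocol of experiment B lists 2i among additions to FBS/LIF, while the titles name LIF alone, and it gives no L-proline dose. Because extraction, vitamin C dose and cell population differed, the experiments were never pooled.

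For experiment A the authors deposited raw counts per Ensembl gene, made with CASAVA, TopHat2 2.0.13 and HTSeq 0.6.1p1 on the mm9 (NCBIM37) build according to the submitters' processing notes. For experiment B the deposited files have the columns of a gene-level mmseq output, and the notes add Bowtie and DESeq without saying which tool made them. Per the file headers and values, each gene has the natural log of an expression value in FPKM units, that is fragments scaled by effective length and mapped total, a count of fragments that hit only this gene (unique hits), and an effective length. The strand setting is not stated. The combined count tables of the authors hold experiment A alone, so the fallback planned for this case, estimated counts, was used for experiment B. Gene symbols came from GENCODE vM21, whose coordinates belong to a later build, so no positions are given.

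Estimated counts of experiment B were computed by taking the deposited natural log values back to FPKM, undoing the scaling by effective length and mapped fragments, and rounding. They summed to 98.7% to 99.5% of the mapped fragments. Among the 7187 genes with at least 100 unique hits in every library, unique hits lay within 5% of the estimate for 79.4%. Of the 16033 genes tested, 344 drew under 10% of their estimate from unique hits, and between 1 and 86 of these were called per comparison.

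Genes were kept by filterByExpr and scaled by TMM. Each comparison was tested with edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3) in 1 model of all 10 libraries with a term per medium, with a Benjamini-Hochberg adjusted p under 0.05 as the threshold. The common biological coefficient of variation was 0.238, on 5 residual degrees of freedom. Standard errors (SE) were derived as the absolute log2 fold change over the square root of F. CPM values are TMM-scaled, with SD over the 2 libraries. Tests are 2-sided.

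Gene lists, 29 in number with 499 different genes, 14 of them without an identifier in the files, were tested with camera (limma 3.58.1). It ran on z-scores that edgeR derives from the counts and fitted dispersions, not on log2 CPM as planned. The preset correlation was 0.01, and p was adjusted over 203 tests. Members were also adjusted over the list alone. Some genes stand on several lists: Tfcp2l1 is a naive gene and a LIF/STAT3 target, T a mesendoderm gene and a Wnt target. Cer1 is on the mesendoderm list and among the Nodal and activin targets. Lists that share members are not separate evidence. With the preset correlation 120 of the 203 tests passed, and 54 of these also passed with a correlation estimated per list. A call is printed with its p under an estimated correlation where it was lost, and every other camera call printed held. A gene without counts in a group is given as a bound against 3 counts over the group, and one with 1 to 3 counts as a ratio with its 95% counting interval. Of the 33 list medians with such a gene, 12 moved when it was placed at its bound, by at most 1.46. Intervals and bounds cover counting error only.

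Genes were named by a fixed rule. In each comparison it took the 5 highest and 5 lowest log2 fold changes among called genes with a symbol, a mean of at least 4 log2 CPM in the higher group and no overlap between the groups, leaving out predicted genes and pseudogenes. From each list it took up to 4 called members with the largest change and up to 2 others with the highest expression, and it added a panel of 9 genes. The groups, comparisons, tests, lists, naming rule and most alternatives were fixed before the data were examined, though the input of camera differed from that plan.

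Effective lengths of replicate 2 libraries were 39.4 to 54.1 bases longer, at the median over genes above 1000 bases, than in FBS/LIF replicate 1, while replicate 1 libraries lay between -1 and 7 bases. The replicate number therefore goes with at least a technical difference between libraries, and the labels do not say whether cultures differed too. Each replicate number holds 1 library per medium, so no comparison can be tested within it. Printed values come from the fit without the replicate number, and counts with it as a block are given beside them. With the block the common biological coefficient of variation was 0.189. Within media, deviations between the libraries exceeded counting error by a chi-square per degree of freedom of 13.3 to 38.0, and Spearman correlations across genes were 0.964 to 0.986.

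In simulated data with 200 changed genes in L-Pro/LIF, edgeR called 146 genes, 4 of them falsely. It recovered 38.2% of 2-fold rises, 88.2% of 4-fold rises and 97% of 8-fold rises, and 30.3%, 75.8% and 97% of the corresponding falls. DESeq2 1.42.0 recovered 165 with 37 false calls. The counts were drawn with edgeR's own dispersions and each library on its own, so the simulation cannot rank edgeR against DESeq2. In the unchanged VitC/LIF group edgeR called 0 genes, and a planted list of 30 genes was the only list called.

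Experiment A ratios are log2 ratios of TMM-scaled CPM with a prior count of 2 over the day 0 library, for genes with a mean of at least 1 CPM, and list medians were ranked among 10000 random lists of the same size matched on expression in 20 bins. Overlaps against the shared FBS/LIF libraries were set beside 10 simulations. Alternatives were RLE size factors, DESeq2, no low-count filter, a mean of at least 1 CPM, only the libraries compared, the replicate block, a 2-fold minimum, limma on the deposited log values with a pseudocount of 0.1, and each library left out. Unique hits, and the fit without F/A replicate 1 for the comparisons that do not involve F/A, were added after the data were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used besides R.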

Results

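RNA sequencing of mouse embryonic stem cells was compared across culture media that hold them at different points between the naive and the primed state of pluripotency. The cells were C57BL/6 dual reporter cells, in which mCherry reports the mir-290 cluster and eGFP the mir-302 cluster. In the first experiment, called experiment B here, cells plated sparsely were grown for 5 days in 5 media, with 2 libraries per medium. FBS/LIF is the base medium with serum and leukemia inhibitory factor, a cytokine that sustains self-renewal. VitC/LIF adds vitamin C at 500 µM, L-Pro/LIF adds L-proline at a dose not stated for these samples, and 2i/LIF adds inhibitors of the MEK kinase and of GSK3. F/A is the serum-free N2B27 medium with activin A at 20 ng/ml and bFGF at 12 ng/ml, the factors in which epiblast-like stem cells are kept. Mapped fragments per library ranged from 17778399 to 26354444, except for 6937945 in F/A replicate 1. In experiment A, 4 single libraries were made from cells described as positive for both reporters, with 33162689 to 39711061 counts each: a day 0 library, L-proline day 5, F/A day 3 and F/A day 5. Nothing in the sample descriptions says whether the 2 libraries of a medium came from separate cultures.

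The pluripotency and early lineage genes fixed as a panel differed strongly between the media. Pou5f1 (ENSMUSG00000024406), the gene of the core pluripotency factor Oct4, stayed within a narrow range, from 485 ± 98 CPM (SD, n = 2) in F/A to 918 ± 110 CPM (SD, n = 2) in 2i/LIF. Esrrb (ENSMUSG00000021255), a naive-state transcription factor, spanned 290 ± 21 CPM in 2i/LIF, 200 ± 44 in VitC/LIF, 163 ± 29 in FBS/LIF, 6.86 ± 1.5 in L-Pro/LIF and 1.21 ± 0.083 in F/A (SD, n = 2 each). T (brachyury), an early mesoderm regulator, ran the other way among VitC/LIF, FBS/LIF, L-Pro/LIF and F/A, from 0.368 ± 0.052 CPM in VitC/LIF to 327 ± 26 CPM in F/A (SD, n = 2). It broke this order in 2i/LIF, at 3.8 ± 0.5 CPM, above VitC/LIF and FBS/LIF.

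**Figure D1:**
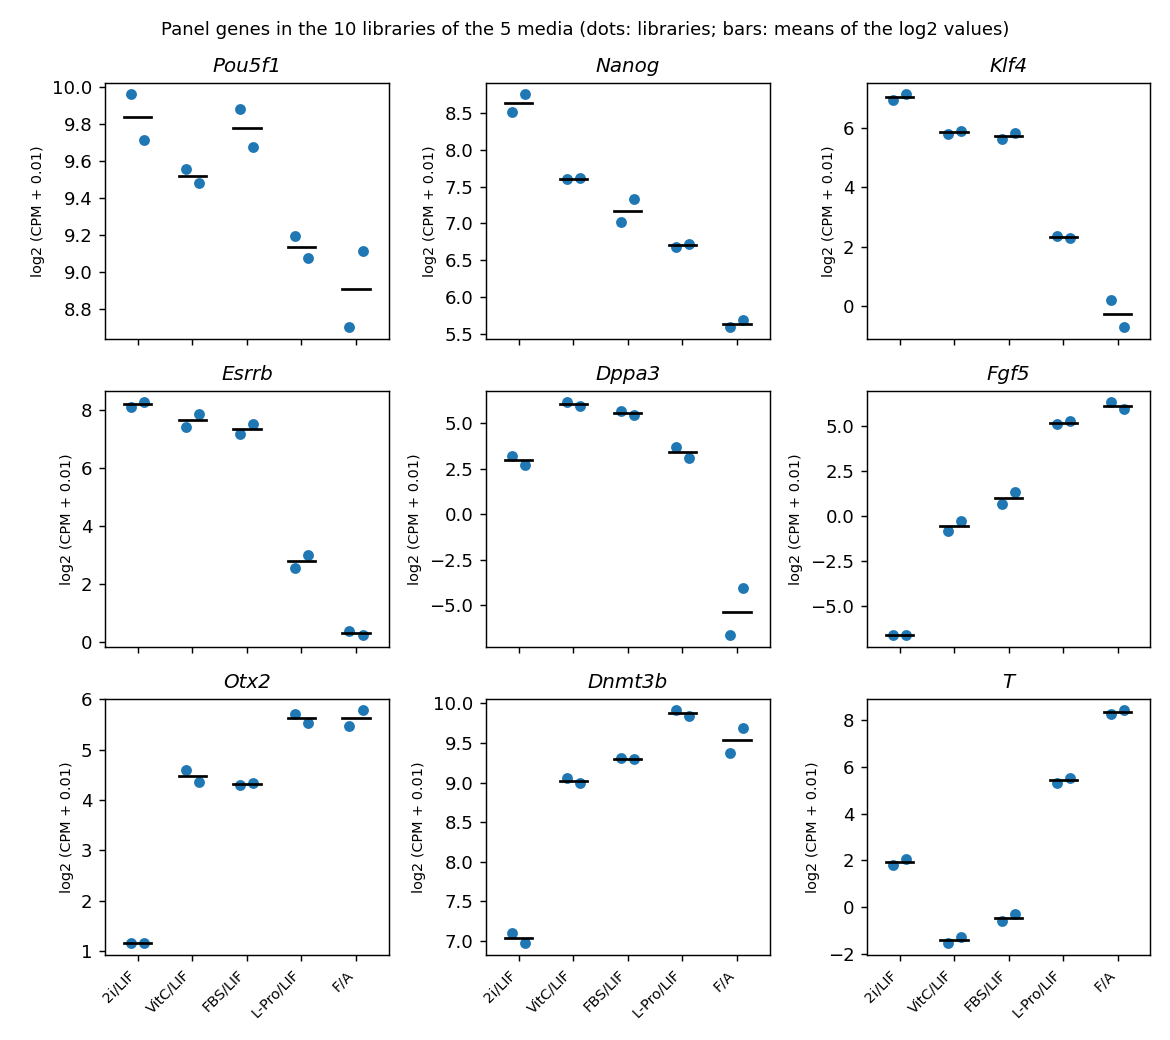
Expression of the 9 panel genes in each of the 10 libraries of experiment B, as log2 of CPM plus 0.01 on the vertical axis (linear in log2 units, scaled per gene), with media on the horizontal axis. Dots are libraries, bars are means of the 2 log2 values, and a library with 0 counts lies at the offset, as Fgf5 does in 2i/LIF. Esrrb means run from 290 CPM in 2i/LIF to 1.21 CPM in F/A.

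The first comparison asked what L-proline changes in FBS/LIF. Cells in L-Pro/LIF had lost most of their naive-state transcripts and carried primed epiblast and early mesendoderm transcripts. Esrrb fell by 4.57 on the log2 scale (SE 0.23, adjusted p = 1.1e-05, log2 fold change -3.39 on unique hits) and Klf4 by 3.41 (SE 0.18, adjusted p = 1.4e-05). Fgf5, a marker of the primed epiblast, rose from 2.1 ± 0.68 to 37.2 ± 2.2 CPM (log2 fold change 4.15, SE 0.26, adjusted p = 4.9e-05). T rose from 0.722 ± 0.11 to 43.3 ± 4.9 CPM (log2 fold change 5.89, SE 0.19, adjusted p = 1.9e-06). Of the 22 naive pluripotency genes, 20 fell and 0 rose, with a median log2 fold change of -2.91 (camera adjusted p = 2.6e-69), and adjusted over the list alone 22 fell. Nr0b1 (log2 fold change -4.23), Jam2 (-3.79) and the nuclear receptor gene Nr5a2 (-3.63) were among them. Klf5 was lower without passing the test (log2 fold change -1.11, SE 0.48, adjusted p = 0.13). The panel genes Dppa3 (-2.13), Otx2 (1.31), Nanog (-0.48), Pou5f1 (-0.65) and the de novo DNA methyltransferase gene Dnmt3b (0.58) also passed the threshold.

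Of the 22 primed epiblast genes, 15 rose and 1 fell (median 1.31, camera adjusted p = 5e-12), or 16 and 2 adjusted over the list alone. Mesendoderm genes went the same way, with 8 of 15 higher, also adjusted over the list alone, and 0 lower (camera adjusted p = 1.8e-08). Their median was 2.34, or 1.80 when the gene without counts in a group is placed at its bound. Wnt3, a signal that precedes gastrulation, rose by 3.82 (SE 0.23), Fgf8 by 5.95 (SE 0.33) and Eomes by 2.40 (SE 0.17) on the log2 scale. Targets of Nodal and activin rose in 9 of 15 cases and fell in 1, with the same counts adjusted over the list alone (median 1.18, or 0.99 at the bound, camera adjusted p = 8.5e-08). Further genes with large rises were Pkdcc (log2 fold change 4.30, SE 0.52, or 2.94 on unique hits) and the Wnt-responsive Sp5 (4.04, SE 0.26). The largest falls with firm read support were those of Inhbb, which encodes an activin subunit (log2 fold change -6.71, SE 0.17), Myo1f (-6.53, SE 0.37) and Mymx (-5.04, SE 0.39, or -5.97 and -4.44 without L-Pro/LIF replicate 1 and 2). Tsnax and Hist1h4m stood among the largest falls too, but 0% of the Tsnax estimate and 0.0089% of the Hist1h4m estimate in FBS/LIF came from reads that hit only that gene, so neither value can be taken as a change of these genes.

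Metabolic and adhesion genes moved as well. Cholesterol synthesis genes rose in 17 of 21 cases, 21 adjusted over the list alone, and 0 fell (median 0.92, camera adjusted p = 1.8e-09), with Msmo1 at a log2 fold change of 1.38 and Cyp51 at 1.33. Epithelial genes rose in 10 of 16 cases and 0 fell (camera adjusted p = 6.3e-09), and 11 rose and 1 fell adjusted over the list alone. The desmosome gene Dsp rose from 30.2 ± 4.8 to 194 ± 38 CPM and the keratin gene Krt8 from 118 ± 10 to 503 ± 11 CPM (SD, n = 2). Collagen and matrix genes rose in 16 of 22 cases and fell in 1 (median 1.08, camera adjusted p = 1.8e-08), 18 and 2 adjusted over the list alone. Igfbp3 (log2 fold change 3.19, SE 0.11), which encodes a binding protein of insulin-like growth factors, was higher too. Markers of fibroblasts, a cell type that feeder layers could add, moved in the same direction: 11 of 16 rose and 1 fell (median 1.33, camera adjusted p = 0.00016), or 11 and 2 adjusted over the list alone. Levels of the markers that rose differed widely in L-Pro/LIF, up to 227 CPM, with Dcn at 3.08 ± 0.4 CPM and Col1a1 at 3.99 ± 0.39 CPM (SD, n = 2). Without FBS/LIF replicate 1 the matrix count was 9 and the fibroblast count 5, with Lox then at an adjusted p of 0.0743, and the fibroblast count was 7 without FBS/LIF replicate 2 and 6 without L-Pro/LIF replicate 1.

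Germline genes whose promoters are silenced by methylation fell in 12 of 24 cases, 14 adjusted over the list alone, and 0 rose (median -1.52, camera adjusted p = 4.4e-11). Among them were the meiotic entry gene Stra8 (log2 fold change -4.17) and Hsf2bp (-3.34). LIF/STAT3 targets fell in 8 of 15 cases, 8 lower and 1 higher adjusted over the list alone (median -1.11, or -0.96 at the bound, camera adjusted p = 1.2e-08). Genes of the ATF4 amino acid response, which answers to amino acid shortage, fell in 21 of 31 cases and rose in 1 (camera adjusted p = 7.3e-09, adjusted p = 0.10 with an estimated correlation), or 23 and 1 adjusted over the list alone, and 11 fell without L-Pro/LIF replicate 1. Trib3 (log2 fold change -1.99) and Chac1 (-2.10) belong to them. The DNA methylation machinery had 5 of 11 genes lower and 1 higher (camera adjusted p = 8.2e-05, adjusted p = 0.076 with an estimated correlation), the same adjusted over the list alone, led by Tet2 (log2 fold change -2.87) and Dnmt3l (-2.68), with 3 lower without FBS/LIF replicate 2 or L-Pro/LIF replicate 1.

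Several other lists passed camera with its preset correlation and lost the call with an estimated one. These were core pluripotency (0 higher and 9 lower of 14, adjusted p = 0.00048, then adjusted p = 0.077), hypoxia response (9 and 1 of 26, 0.002, then 0.13), p53 targets (11 and 1 of 20, 0.00052, then 0.19) and Wnt targets (8 and 1 of 18, 1.2e-05, then 0.12). Glycolysis (7 and 1 of 19, 0.03, then 0.45), mesenchymal genes (7 and 1 of 18, 0.02, then 0.17) and oxidative phosphorylation (0 and 3 of 27, 0.039, then 0.71) did so too. Adjusted over the list alone, these 7 lists in the same order had 1 and 10, 13 and 1, 11 and 1, 8 and 2, 9 and 1, 10 and 1, and 0 and 0 members higher and lower. Slc2a3 and Egln1 of the hypoxia list rose by 1.44 and 1.58 on the log2 scale, and Tap1 of the p53 list by 2.32. Without L-Pro/LIF replicate 1 the core count was 5, the glycolysis count 3 and the Wnt count 5. The core count was also 5 without FBS/LIF replicate 2 or L-Pro/LIF replicate 2, as was the Wnt count, while 4 glycolysis genes rose without either FBS/LIF library. Mesenchymal genes rose in 3 cases without FBS/LIF replicate 1 or L-Pro/LIF replicate 2, and 0 oxidative phosphorylation genes fell without any 1 of the 4 libraries.

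The remaining lists did not pass camera in this comparison. These were imprinted genes (6 higher and 2 lower of 20, adjusted p = 0.23), BMP targets (0 and 2 of 12, 0.22), trophectoderm (4 and 2 of 12, 0.39), neuroectoderm (1 and 1 of 7, 0.75), primitive endoderm (5 and 1 of 19, 0.59) and genes of the 2-cell-like state (0 and 2 of 5, 0.1). The JmjC histone demethylases (1 and 3 of 18, adjusted p = 0.52), proline metabolism (4 and 2 of 15, 0.95), FGF/ERK targets (5 and 4 of 18, 0.79) and the transcripts of the mitochondrial genome (0 and 3 of 13, 0.15) did not pass either. Adjusted over the list alone only imprinted genes (7 and 2), 2-cell-like genes (0 and 3), FGF/ERK targets (5 and 6) and mitochondrial transcripts (0 and 5) had other counts. Median, mean and test direction differed in sign for FGF/ERK targets (median -0.19, mean 0.02), mitochondrial transcripts (median -0.28, mean 0.3, tested as lower) and primitive endoderm (median and mean -0.01, tested as higher). Without 1 library, FGF/ERK targets had 2 to 4 members higher and 0 or 1 lower, primitive endoderm 2 to 5 higher, trophectoderm 2 or 3 higher, JmjC demethylases 1 lower and mitochondrial transcripts 0 or 1 lower, whichever of the 4 libraries was left out.

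In all, 3855 of the 16033 genes tested differed between L-Pro/LIF and FBS/LIF, 2198 higher and 1657 lower, and 3730 with the replicate number as a block. With each library left out the count was 2002 without FBS/LIF replicate 1, 2238 without FBS/LIF replicate 2, 2027 without L-Pro/LIF replicate 1 and 2106 without L-Pro/LIF replicate 2. Pou5f1 and Dnmt3b each lost the call without any 1 of these libraries, at adjusted p of 0.0556 to 0.162 and 0.0662 to 0.139. Nanog lost it without FBS/LIF replicate 2 (adjusted p = 0.239), L-Pro/LIF replicate 1 (0.18) or L-Pro/LIF replicate 2 (0.146).

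**Figure D2:**
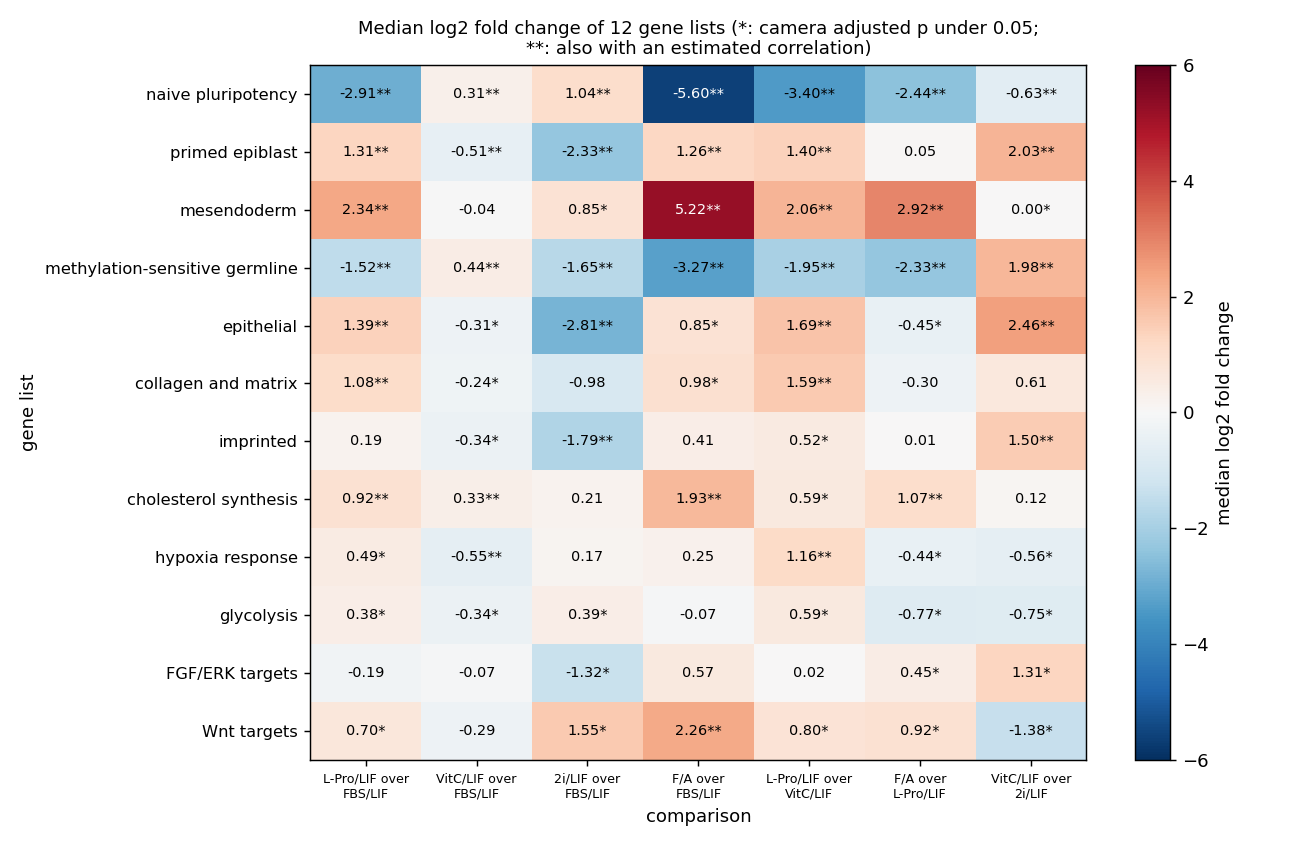
Median log2 fold change of the members of 12 gene lists (vertical axis) in the 7 comparisons (horizontal axis), printed in each cell and shaded from blue (lower) to red (higher). A single star marks a camera adjusted p under 0.05, and a double star one that also holds with an estimated correlation. The naive pluripotency row runs from -5.60 for F/A over FBS/LIF to 1.04 for 2i/LIF over FBS/LIF.

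What vitamin C changes in FBS/LIF was the second question, and its effect on the transcriptome was small. No panel gene passed the threshold with edgeR: Nanog was at 195 ± 0.97 against 145 ± 22 CPM (log2 fold change 0.42, SE 0.14, adjusted p = 0.25) and Fgf5 at 0.681 ± 0.18 against 2.1 ± 0.68 CPM (log2 fold change -1.62, SE 0.32, adjusted p = 0.088), which did pass with DESeq2 (adjusted p = 0.00498). Genes of the hypoxia response, whose regulating hydroxylases use vitamin C as a cofactor, fell in 5 of 26 cases and 0 rose (median -0.55, camera adjusted p = 2.3e-11), or 13 lower and 1 higher adjusted over the list alone. Bnip3, a mitophagy receptor gene, fell from 81.2 ± 2.7 to 32.2 ± 0.53 CPM (log2 fold change -1.33, SE 0.20, adjusted p = 0.029). The lactate dehydrogenase gene Ldha fell from 1229 ± 23 to 595 ± 17 CPM (SD, n = 2). The collagen prolyl hydroxylase gene P4ha1 fell by 1.11 and the glucose transporter gene Slc2a1 by 0.86 on the log2 scale. Glycolysis genes fell in 4 of 19 cases (camera adjusted p = 0.0038, adjusted p = 0.32 with an estimated correlation), with Pfkl at a log2 fold change of -1.25. Adjusted over the list alone 4 were higher and 9 lower. The called Ldha, Slc2a1 and Eno1 are on the hypoxia list too, as are Slc2a3 and Aldoa. These lists are therefore not separate evidence in any comparison.

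Methylation-sensitive germline genes went up, 3 of 24 higher and 0 lower (median 0.44, camera adjusted p = 2.7e-10), or 10 higher and 2 lower adjusted over the list alone. Stra8 rose from 4.72 ± 0.91 to 25 ± 1.5 CPM, the RNA-binding protein gene Dazl from 8.35 ± 0.68 to 21.5 ± 0.85 CPM and Rpl10l from 25.4 ± 2.4 to 58 ± 4.5 CPM (SD, n = 2), the call of Rpl10l being lost with the replicate block (adjusted p = 0.057). Naive genes rose in 2 of 22 cases, Tbx3 by 1.54 and Pecam1 by 0.70 on the log2 scale, and 6 adjusted over the list alone (median 0.31, camera adjusted p = 6.1e-07), but Pecam1 did not pass on unique hits (adjusted p = 0.0648). Primed epiblast genes fell in 2 of 22 cases, Sall2 by 0.89 and Igfbp3 by 0.70, and 7 adjusted over the list alone (median -0.51, camera adjusted p = 8.4e-08). The 5 measured 2-cell-like genes had a median of 1.86 (camera adjusted p = 2.9e-08, 4 higher adjusted over the list alone). Only Zscan4f passed over all genes, at 12% unique reads (log2 fold change 1.85, SE 0.26). On unique hits its log2 fold change was 2.33 without passing (adjusted p = 0.0689). Cholesterol synthesis genes had 0 calls over all genes and 3 higher adjusted over the list alone (median 0.33, camera adjusted p = 7.1e-06). Imprinted genes fell in 2 of 20 cases, Cdkn1c by 1.03 and Phlda2 by 1.02, or 3 higher and 6 lower adjusted over the list alone (camera adjusted p = 0.0061, adjusted p = 0.072 with an estimated correlation). Besides Stra8, Mep1b (log2 fold change 2.84), Cyp2b23 (2.25), Gstp2 (2.10) and the smooth muscle actin gene Acta2 (2.04), one of the fibroblast markers, were among the largest rises, and Enpp2 (-2.69), Spink1 (-2.07), the hyaluronan synthase gene Has2 (-1.91) and Nefl (-1.38) fell most among genes with unique reads, though Spink1 lost the call with the replicate block (adjusted p = 0.05). Dnmt3l, a partner of the de novo methyltransferases, fell from 304 ± 4 to 159 ± 0.27 CPM (log2 fold change -0.93, SE 0.13, adjusted p = 0.022).

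The count behind this was 108 genes, 58 higher and 50 lower, and 86 with the replicate number as a block. It rested on every library: 9 genes passed without FBS/LIF replicate 1, 12 without FBS/LIF replicate 2, 10 without VitC/LIF replicate 1 and 6 without VitC/LIF replicate 2, and no member of the hypoxia, glycolysis, germline, naive, primed, 2-cell-like or imprinted lists did in any of these fits. Of the 24 genes named here that passed, 22 lost the call in at least 1 of those fits, Gstp2 and Enpp2 being the exceptions. The log2 fold changes of these genes kept their sign in those fits, which have 1 library in a medium. Ldha lay between -1.074 and -1.014 and Bnip3 between -1.364 and -1.295, while Spink1 ranged from -2.433 to -1.709 and Tbx3 from 1.305 to 1.824. DESeq2 called 408 genes here. In data simulated for another comparison, L-Pro/LIF over FBS/LIF, it made 37 false calls against 4 for edgeR, and recovered 165 changed genes against 142. Those data were drawn with edgeR's own dispersions, and false calls of DESeq2 for VitC/LIF were not counted. They therefore cannot tell how many of the 408 are false.

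In 2i/LIF against FBS/LIF, the third comparison, naive genes were higher and epithelial, primed and imprinted genes lower. Nanog rose from 145 ± 22 to 397 ± 46 CPM (log2 fold change 1.45, SE 0.14, adjusted p = 0.0001) and Klf4 by 1.30 (SE 0.17). Otx2, a primed-state factor, fell by 3.15 (SE 0.16) and Dnmt3b by 2.27 (SE 0.14). Dppa3, although a naive marker, fell from 47.2 ± 5.6 to 7.92 ± 1.8 CPM (log2 fold change -2.57, SE 0.25). Fgf5 had no counts in 2i/LIF and was at least 25.7-fold lower, while T rose by 2.38 (SE 0.19). Esrrb rose by 0.83 (SE 0.20, adjusted p = 0.014), a call lost without FBS/LIF replicate 1 (adjusted p = 0.0968) or 2i/LIF replicate 2 (0.0822). Pou5f1 stood at 918 ± 110 against 882 ± 91 CPM (log2 fold change 0.06, SE 0.17, adjusted p = 0.83).

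Epithelial genes fell in 14 of 16 cases and 0 rose, 15 lower adjusted over the list alone (median -2.81, camera adjusted p = 2.1e-24). The splicing regulator gene Esrp1 fell from 60.7 ± 6.7 to 0.33 ± 0.17 CPM, and the log2 fold change was -4.92 for the transcription factor gene Grhl2 and -4.33 and -4.22 for the claudin genes Cldn6 and Cldn7. Primed epiblast genes fell in 16 of 22 cases and rose in 2, or 18 and 2 adjusted over the list alone (median -2.33, camera adjusted p = 9.5e-18). Imprinted genes fell in 13 of 20 cases and rose in 2, or 15 and 2 adjusted over the list alone (median -1.79, camera adjusted p = 6.2e-10), with the growth restrainer Cdkn1c at a log2 fold change of -4.97 and Phlda2 at -4.71. Naive genes rose in 17 of 22 cases and fell in 2, the same adjusted over the list alone (median 1.04, camera adjusted p = 1.6e-08), including Tbx3 (2.96), Tfcp2l1 (2.34) and Spic (3.54).

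The targets of the pathways that 2i acts on moved in opposite directions. FGF/ERK targets, downstream of MEK, fell in 13 of 18 cases and rose in 1, or 15 and 1 adjusted over the list alone (camera adjusted p = 6.6e-07, adjusted p = 0.08 with an estimated correlation), with the phosphatase gene Dusp4 at a log2 fold change of -4.11 and Spry4 at -3.53. Wnt targets, which inhibition of GSK3 activates, rose in 9 of 18 cases and fell in 3, or 10 and 5 adjusted over the list alone (camera adjusted p = 4.2e-06, adjusted p = 0.08 with an estimated correlation), with Axin2 at 3.47 and Sp5 at 3.44, and 1 fell without 2i/LIF replicate 1. Nkx1-2 (6.65), Sh2d4b (5.87), Cdx1 (5.39), Myo1a (5.16) and Trpm1 (5.04, or 5.80 on unique hits) had the largest rises, and Enpp3 (-6.35), Enpp2 (-5.95, or -6.71 without 2i/LIF replicate 2), Spink1 (-5.80) and the hedgehog effector gene Gli1 (-5.69) followed Esrp1 among the falls. Germline genes fell in 14 of 24 cases and rose in 1, or 15 and 4 adjusted over the list alone (median -1.65, camera adjusted p = 8.5e-05), Tdrd1 by 4.86 and Stra8 by 3.1, and 9 fell without 2i/LIF replicate 1, where Tdrd1 was at -5.59. Dnmt3a, the other de novo methyltransferase gene, fell by 2.77 (SE 0.23). Fibroblast markers fell in 6 of 16 cases and rose in 1, or 7 and 2 adjusted over the list alone (median -2.10, or -1.55 at the bound, camera adjusted p = 0.0072, adjusted p = 0.077 with an estimated correlation). Altogether 4864 genes differed, 1997 higher and 2867 lower, and 4747 with the replicate block. The count was 2932 without 2i/LIF replicate 1, 3048 without 2i/LIF replicate 2 and 3196 without FBS/LIF replicate 2.

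The fourth comparison set F/A against FBS/LIF, which differ in basal medium, serum and LIF besides the added factors. Most naive transcripts were much lower and most mesendoderm transcripts higher in F/A. Esrrb fell by 7.09 (SE 0.28, adjusted p = 7.3e-07) and Klf4 by 6.08 (SE 0.24, adjusted p = 6.5e-07, log2 fold change -4.62 on unique hits) on the log2 scale. For Dppa3, with 1 count in F/A, the ratio was 1320-fold with a counting interval of 236 to 52000. T rose from 0.722 ± 0.11 to 327 ± 26 CPM (log2 fold change 8.81, SE 0.20, adjusted p = 8.2e-08) and Fgf5 to 72.1 ± 13 CPM (5.1, SE 0.26). Otx2 rose by 1.32, Nanog fell by 1.54 and Pou5f1 fell by 0.86. Dnmt3b was at 747 ± 120 against 632 ± 1.5 CPM (log2 fold change 0.24, SE 0.13, adjusted p = 0.17), with an adjusted p of 0.0234 without F/A replicate 1 and a log2 fold change of -0.02 without F/A replicate 2.

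Of the 22 naive genes, 20 fell and 0 rose, also adjusted over the list alone (median -5.60, camera adjusted p = 1.9e-63), among them Dppa5a (-9.01, or -9.66 without F/A replicate 2), Zfp42 (-8.04), better known as Rex1, and Nr0b1 (-7.98). Mesendoderm genes rose in 14 of 15 cases and 0 fell, also adjusted over the list alone (median 5.22, camera adjusted p = 7e-18), including Mixl1 (7.40) and Lhx1 (8.47, or 7.49 and 12.35 without FBS/LIF replicate 1 and 2). The endoderm signal antagonist gene Cer1, without counts in FBS/LIF, was at least 60.2-fold higher. All 21 cholesterol synthesis genes rose, also adjusted over the list alone (median 1.93, camera adjusted p = 3.2e-22), Stard4 by 3.24 and Hsd17b7 by 3.06, in a medium without serum. Wnt targets rose in 15 of 18 cases and fell in 1 (median 2.26, camera adjusted p = 2.3e-09), mesenchymal genes rose in 12 of 18 and 0 fell (median 2.11, camera adjusted p = 1.4e-05), and both counts were the same adjusted over the list alone. The mesenchymal genes Tnc (4.83) and Zeb2 (4.17) were examples, and Nkx1-2 (7.30) and Cdh2 (4.25), both on the primed epiblast list, rose too. Primed epiblast genes rose in 14 of 22 cases and fell in 4, or 14 and 5 adjusted over the list alone (median 1.26, camera adjusted p = 1.6e-08), with 2 lower without FBS/LIF replicate 2. Primitive endoderm genes rose in 11 of 19 cases and fell in 1, also adjusted over the list alone (median 1.38, camera adjusted p = 0.0012, adjusted p = 0.31 with an estimated correlation), and Sox17 rose by 3.31, or 3.92 without FBS/LIF replicate 2.

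Germline genes fell in 20 of 24 cases and rose in 1 (median -3.27, camera adjusted p = 9.3e-18), LIF/STAT3 targets fell in 10 of 15 cases and 0 rose (median -2.15, camera adjusted p = 1.6e-12), and core pluripotency genes fell in 10 of 14 cases and rose in 1 (median -1.04, camera adjusted p = 2.5e-10). Adjusted over the list alone these 3 counts were the same. Sox2 fell from 665 ± 5.2 to 60.6 ± 19 CPM and Dppa2 by 8.02 on the log2 scale. Oxidative phosphorylation genes fell in 20 of 27 cases, also adjusted over the list alone (median -0.66, camera adjusted p = 0.00075, adjusted p = 0.55 with an estimated correlation), Cox4i1 by 1.53. That count was 5 without FBS/LIF replicate 1 and 13 without F/A replicate 1, the shallowest library. Nodal and activin targets went both ways, with 6 higher and 7 lower of 15 (median -0.17, mean 1.2, camera adjusted p = 1). Adjusted over the list alone, 7 were higher and 7 lower. The activin antagonist gene Fst, on the primitive endoderm list, was higher by 4.24. Among single genes, Aplnr, without counts in FBS/LIF, was at least 443-fold higher, Pcdh7 rose by 9.26 (SE 0.50, or 8.58 and 10.45 without FBS/LIF replicate 1 and 2), and Foxb1, with 2 counts in FBS/LIF, was 395-fold higher with a counting interval of 109 to 3270. The keratin gene Krt42 had no counts in F/A and was at least 318-fold lower. The ratios of Ooep and Rpl39l, each with 1 count in F/A, were 1810 (counting interval 324 to 71500) and 790 (141 to 31200), and Dnmt3l fell by 9.43 (SE 0.21). In total 7441 genes differed, 3917 higher and 3524 lower, and 7300 with the replicate block, against 4345 without FBS/LIF replicate 1. Scaling by library size alone would move the median of all genes by 0.21 here and by 0.175 in F/A over L-Pro/LIF.

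Placed directly against each other, the metabolites of the series title gave the fifth comparison. L-Pro/LIF cells were low in naive and germline genes and high in primed, epithelial, matrix and hypoxia response genes relative to VitC/LIF cells. Esrrb was lower by 4.87 (SE 0.24, adjusted p = 5.3e-06, log2 fold change -3.80 on unique hits), Klf4 by 3.52, Dppa3 by 2.63 and Nanog by 0.90. T was higher by 6.86 (SE 0.21, adjusted p = 9.8e-07), Fgf5 by 5.76, Otx2 by 1.14 and Dnmt3b by 0.85. Pou5f1, at 563 ± 33 against 735 ± 27 CPM, did not pass (log2 fold change -0.39, SE 0.17, adjusted p = 0.12). Naive genes were lower in 21 of 22 cases and higher in 0 (median -3.40, camera adjusted p = 1.9e-63). Germline genes were lower in 14 of 24 cases and higher in 1 (median -1.95, camera adjusted p = 2.3e-14), and both lists had the same counts adjusted over the list alone. Stra8 fell from 25 ± 1.5 to 0.259 ± 0.087 CPM, Hormad1 from 22.4 ± 1.1 to 0.779 ± 0.13 CPM and Rpl10l from 58 ± 4.5 to 3.33 ± 0.49 CPM (SD, n = 2).

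Primed epiblast genes were higher in 15 of 22 cases and lower in 1, or 17 and 1 adjusted over the list alone (median 1.40, camera adjusted p = 7e-15). Mesendoderm genes were higher in 8 of 15 cases and lower in 1, also adjusted over the list alone (median 2.06, or 1.84 at the bound, camera adjusted p = 5.5e-06), with 5 higher without VitC/LIF replicate 2. Epithelial genes were higher in 11 of 16 cases, 12 adjusted over the list alone, and lower in 0 (camera adjusted p = 3e-10), Dsp by 2.96 and Krt8 by 2.43. Hypoxia response genes were higher in 16 of 26 cases and lower in 1, or 17 and 2 adjusted over the list alone (median 1.16, camera adjusted p = 1.6e-07). Ddit4 (2.31), Pfkfb3 (2.30), the oxygen sensor gene Egln1 (2.11) and P4ha1 (2.05) led that list. Glycolysis genes were higher in 9 of 19 cases and lower in 3, or 12 and 3 adjusted over the list alone (camera adjusted p = 0.0026, adjusted p = 0.32 with an estimated correlation), Pfkl by 2.13 and Slc2a1 by 2.04, with 1 lower without L-Pro/LIF replicate 2 or VitC/LIF replicate 1. Collagen and matrix genes were higher in 16 of 22 cases, or 17 higher and 1 lower adjusted over the list alone (median 1.59, camera adjusted p = 2.1e-09). Beside them, fibroblast markers were higher in 8 of 16 cases and lower in 1, also adjusted over the list alone (camera adjusted p = 0.0094, adjusted p = 0.082 with an estimated correlation). Col3a1, on both lists, was at 2.86 ± 0.48 CPM against 1 count in VitC/LIF, a ratio of 102 with a counting interval of 18 to 4070. The 2-cell-like genes were lower in 3 of 5 cases, 4 adjusted over the list alone (camera adjusted p = 0.00075, adjusted p = 0.067 with an estimated correlation), and in 5 without L-Pro/LIF replicate 2. After T and Fgf5, and Stra8 among the lower genes, large differences were those of Slc39a8 (5.21), Sp5 (4.88) and Wnt3 (4.53) on the higher side and Inhbb (-7.37), Myo1f (-6.79), Khdc3 (-6.61) and Mep1b (-5.84) on the lower. The 4779 genes called comprised 2692 higher and 2087 lower, with 4682 under the replicate block. Leaving out a library gave 2983 (L-Pro/LIF replicate 1), 3056 (L-Pro/LIF replicate 2), 2860 (VitC/LIF replicate 1) and 2911 (VitC/LIF replicate 2).

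How far L-Pro/LIF cells lie from F/A cells was the sixth question. F/A cells had less of the naive genes that remained in L-Pro/LIF and more mesendoderm transcripts. T was higher by 2.92 (SE 0.14, adjusted p = 9.9e-06), while Klf4 was lower by 2.67 (SE 0.24), Esrrb by 2.52 (SE 0.27) and Nanog by 1.06 (SE 0.14). On unique hits the log2 fold changes of Klf4 and Esrrb were -1.16 and -3.76, and both still passed. Dppa3, with 1 count in F/A, was 297-fold lower with a counting interval of 53 to 11700. Fgf5 was higher by 0.95 (SE 0.21, adjusted p = 0.022), which did not pass without L-Pro/LIF replicate 1 (adjusted p = 0.145), L-Pro/LIF replicate 2 (0.0837) or F/A replicate 1 (0.115). Otx2 was at 49.7 ± 7.3 against 49.3 ± 4.2 CPM (log2 fold change 0.02, SE 0.14, adjusted p = 0.94), Pou5f1 at 485 ± 98 against 563 ± 33 CPM (adjusted p = 0.37) and Dnmt3b at 747 ± 120 against 942 ± 32 CPM (adjusted p = 0.1). Without F/A replicate 2 both Pou5f1 (log2 fold change -0.53, adjusted p = 0.0261) and Dnmt3b (-0.60, adjusted p = 0.00496) passed. Primed epiblast genes as a list did not differ by camera (5 higher and 2 lower of 22, or 6 and 5 adjusted over the list alone, median 0.05, adjusted p = 0.18), and 2 were higher without L-Pro/LIF replicate 1 and 3 without L-Pro/LIF replicate 2. The lower count ranged from 0 without L-Pro/LIF replicate 2 to 6 without F/A replicate 2.

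Naive genes were lower in 16 of 22 cases and higher in 2, or 17 and 2 adjusted over the list alone (median -2.44, camera adjusted p = 2.1e-24), Dppa5a by 6.41 (log2 fold change -7.05 without F/A replicate 2) and Zfp42 by 4.98, with 0 higher without F/A replicate 1 or either L-Pro/LIF library. Core pluripotency genes were lower in 7 of 14 cases and higher in 1, also adjusted over the list alone (median -0.44, camera adjusted p = 1.4e-10), with Dppa2 at -6.49. Mesendoderm genes were higher in 12 of 15 cases, 13 adjusted over the list alone, and lower in 0 (median 2.92, camera adjusted p = 8.5e-18). Lhx1 (8.61) and the endoderm factor gene Foxa2 (5.00) were among the largest rises with Aplnr (7.28) and Dgkk (4.76), and Cer1, with 3 counts in L-Pro/LIF, was 67-fold higher with a counting interval of 22.4 to 330. Without L-Pro/LIF replicate 1 and 2, Lhx1 was at 7.69 and 12.32 and Foxa2 at 6.70 and 4.18, and Dgkk was at 3.86 without F/A replicate 1. Cholesterol synthesis genes were higher in 20 of 21 cases, also adjusted over the list alone, and lower in 0 (median 1.07, camera adjusted p = 2.2e-18), Stard4 by 2.04 and Hsd17b7 by 1.77. Nodal and activin targets were lower in 8 of 15 cases and higher in 4, or 9 and 4 adjusted over the list alone (median -0.64, camera adjusted p = 6.5e-07). The Nodal inhibitor genes Lefty1 and Lefty2 stood at 21.4 ± 1.7 against 456 ± 33 CPM and 8.66 ± 0.77 against 218 ± 9.8 CPM (SD, n = 2), and Gdf3 was lower by 3.65. BMP targets were lower in 6 of 12 cases, also adjusted over the list alone, and higher in 0 (median -1.47, camera adjusted p = 0.00014), Id1 by 2.03.

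ATF4 response genes were higher in 16 of 31 cases and lower in 0, or 16 and 1 adjusted over the list alone (camera adjusted p = 2.1e-07, adjusted p = 0.14 with an estimated correlation), the cystine transporter gene Slc7a11 by 2.79. Glycolysis genes were lower in 11 of 19 cases and higher in 0, or 13 and 0 adjusted over the list alone (camera adjusted p = 7.3e-06, adjusted p = 0.14 with an estimated correlation), Pfkp by 1.56 and Slc2a1 by 1.19. Dnmt3l was lower by 6.75 (SE 0.20), and Rex2 (-4.73, or -6.62 on unique hits) and Clrn1 (5.63) had 10.5% and 5.2% unique reads, Clrn1 no longer passing on unique hits (log2 fold change 2.39, adjusted p = 0.0873). It did not pass either without L-Pro/LIF replicate 1 (log2 fold change 8.60, adjusted p = 0.0804), L-Pro/LIF replicate 2 (4.63, 0.118) or F/A replicate 1 (3.57, 0.15). The comparison called 3529 genes, 1785 higher and 1744 lower, and 3237 with the replicate block. Both the count and its even split were sensitive to single libraries. It was 752 (220 higher and 532 lower) without L-Pro/LIF replicate 1, 1183 (451 and 732) without L-Pro/LIF replicate 2, 1598 (629 and 969) without F/A replicate 1 and 6296 (2547 and 3749) without F/A replicate 2. Without L-Pro/LIF replicate 1 the lists gave 7 higher mesendoderm, 13 higher cholesterol, 8 higher ATF4 and 3 lower glycolysis genes, the last being 7 without L-Pro/LIF replicate 2.

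VitC/LIF and 2i/LIF were set against each other in the seventh comparison. VitC/LIF cells had higher epithelial, primed, germline and imprinted transcripts. Dppa3 was higher by 3.08 (SE 0.25, adjusted p = 6.8e-05), Otx2 by 3.32 and Dnmt3b by 1.99, and Fgf5, without counts in 2i/LIF, was at least 8.33-fold higher. T was lower by 3.35 (SE 0.22), Klf4 by 1.19 and Nanog by 1.03. Esrrb, at 200 ± 44 against 290 ± 21 CPM, did not pass (log2 fold change -0.53, SE 0.20, adjusted p = 0.087), though it did with the replicate block (adjusted p = 0.0204), DESeq2 (0.043) and unique hits (0.0397), and Pou5f1 did not either (735 ± 27 against 918 ± 110 CPM, adjusted p = 0.2). Epithelial genes were higher in 13 of 16 cases and lower in 0, also adjusted over the list alone (median 2.46, camera adjusted p = 2.1e-24), Esrp1 by 7.32, or 7.93 without 2i/LIF replicate 2, and Grhl2 by 4.48. Primed epiblast genes were higher in 15 of 22 cases and lower in 1, or 16 and 4 adjusted over the list alone (median 2.03, camera adjusted p = 2.3e-14). Germline genes were higher in 19 of 24 cases and lower in 0, also adjusted over the list alone (median 1.98, camera adjusted p = 6e-13), including Stra8 (5.50), Smc1b (4.09) and Tdrd1 (3.99, or 4.72 without 2i/LIF replicate 1). Imprinted genes were higher in 12 of 20 cases and lower in 1, or 14 and 1 adjusted over the list alone (median 1.5, camera adjusted p = 1.1e-09), with Cdkn1c at 3.94 and Phlda2 at 3.70.

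Naive genes were lower in 13 of 22 cases and higher in 2, or 15 and 2 adjusted over the list alone (median -0.63, camera adjusted p = 2.3e-05), Tfcp2l1 by 1.70 and Jam2 by 1.69. Wnt targets were lower in 9 of 18 cases and higher in 2, or 10 and 2 adjusted over the list alone (camera adjusted p = 7.3e-09, adjusted p = 0.053 with an estimated correlation), Sp5 by 4.28 and Axin2 by 3.53. FGF/ERK targets were higher in 13 of 18 cases, 14 adjusted over the list alone, and lower in 0 (median 1.31, or 1.26 at the bound, camera adjusted p = 1.8e-08, adjusted p = 0.057 with an estimated correlation), Dusp4 by 4.02, with 8 higher without 2i/LIF replicate 2. Hypoxia response genes were lower in 11 of 26 cases and higher in 1, or 12 and 2 adjusted over the list alone (camera adjusted p = 0.0012, adjusted p = 0.12 with an estimated correlation), P4ha1 by 1.37. Glycolysis genes were lower in 13 of 19 cases and higher in 1, or 14 and 1 adjusted over the list alone (camera adjusted p = 7.8e-05, adjusted p = 0.2 with an estimated correlation), the aldolase gene Aldoa by 1.35. Fibroblast markers were higher in 5 of 16 cases and lower in 1, or 5 and 2 adjusted over the list alone (median 1.55, or 1.15 at the bound, camera adjusted p = 0.00075). The smooth muscle gene Tagln (5.32), Enpp3 (5.69) and Phf19 (5.23) were among the largest rises, Nkx1-2 (-7.60), Cdx1 (-4.73) and Sh2d4b (-4.22) among the largest falls. Hist1h4m also passed (adjusted p = 0.047), with near 0 unique reads and no call without VitC/LIF replicate 1 (adjusted p = 0.0985), VitC/LIF replicate 2 (0.202) or 2i/LIF replicate 2 (0.408), nor with the replicate block (0.0997) or DESeq2 (0.158). The comparison called 3935 genes, 2392 higher and 1543 lower, and 3774 with the replicate block. The count was 2301 without VitC/LIF replicate 1, 2195 without VitC/LIF replicate 2, 2150 without 2i/LIF replicate 1 and 2258 without 2i/LIF replicate 2.

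Effects measured against FBS/LIF share their 2 control libraries, so their overlap was set beside simulated data and beside the overlap of independent calls. In the simulated data FBS/LIF and the 2 other media were all drawn as unchanged groups, around the mean of FBS/LIF. Each library was drawn on its own, so the correlation by replicate number seen in the real data was left out. Of the 2198 genes higher in L-Pro/LIF, 1718 were also higher in F/A, where independent calls would share 537 and simulated groups shared at most 1. Of the 1657 lower genes, 1374 were also lower in F/A against 364.2 for independent calls, and 41 genes went opposite ways. Across genes, which are not independent replicates, the Pearson correlation was 0.70 and the covariance 1.32, against 0.47 and 0.163 in the simulations. L-Pro/LIF and VitC/LIF effects shared 8 higher and 7 lower genes, against 8 and 5.2 for independent calls, while 71 genes moved in opposite directions. Their correlation was 0.05 against 0.50 in simulation, and their covariance was 0.119 below the simulated one. Of the 58 genes higher in VitC/LIF, 46 were higher in 2i/LIF, and of the 50 lower genes, 40 were lower there, against 7.2 and 8.9 for independent calls, with 6 going opposite ways. Across all genes their correlation was 0.42 against 0.48 in simulation, while their covariance was 0.439 against 0.163. Simulated groups differ by noise alone, so the controls they share fix their correlation near such a value. The correlations of real effects therefore cannot be ranked against the simulated ones. The shared controls cannot be split between the comparisons, so any part they add remains in these overlaps.

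Experiment A gave single libraries and therefore log2 ratios without a test. Over the 13533 genes at a mean of at least 1 CPM, 2597 were at least 2-fold higher and 1820 at least 2-fold lower in L-proline day 5 than at day 0. F/A day 3 had 2233 and 1549 such genes, and F/A day 5 had 2685 and 1950. Esrrb went from 664 CPM at day 0 to 23.4 CPM with L-proline, a log2 ratio of -4.82 with a counting interval of -4.92 to -4.73, and to 1.62 CPM in F/A day 5. T went from 0.723 to 52.4 CPM with L-proline (log2 ratio 6.07, interval 5.60 to 6.82) and to 845 CPM in F/A day 5. Fgf5 had a log2 ratio of 6.38 with L-proline (interval 5.64 to 8.22), and of 8.38 and 8.99 at F/A day 3 and day 5. Otx2 was near its day 0 level with L-proline, at -0.12 with an interval of -0.26 to 0.02, and Dppa3 at -0.78, -1.79 and -6.27 in the order of the 3 libraries. For Pou5f1 the ratios were -0.49, -0.29 and -0.60, for Nanog -1.92, -0.99 and -1.93, for Klf4 -3.17, -6.19 and -3.07, and for Dnmt3b 0.92, 1.67 and 0.47. Among other genes, Krt8 (7.75), Dsp (4.21) and Igfbp3 (6.08) were higher and Inhbb (-7.52) and Stra8 (-9.38) lower with L-proline.

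The lists were read in experiment A as medians against random lists of matched expression. Naive genes had medians of -4.29, -4.61 and -6.27 in L-proline day 5, F/A day 3 and F/A day 5, each below all 10000 random lists. Mesendoderm medians were 2.89, 1.66 and 6.49, and primed epiblast medians 0.92, 2.07 and 1.57, with 99.0 to 100% of random lists below them. Germline genes had medians of -3.23, -0.81 and -5.79, and epithelial genes of 2.48, 0.88 and 2.12. Imprinted genes were higher in all 3 libraries, with medians of 1.65, 1.65 and 1.44, and so were p53 targets, with 1.45, 1.2 and 1.64. Hypoxia response and glycolysis medians were -0.42 and -0.58 with L-proline, below 99.8% and all of the random lists. At F/A day 3 and day 5 they were 0.02 and 0.40 for hypoxia response, the latter above 99.3% of random lists, and -0.09 and 0.01 for glycolysis. Fibroblast markers had a median of 0.24 with L-proline, above 66.9% of random lists.

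Whether the separate experiments moved the same way was described across genes, which are not replicates. Because day 0 cells had been kept in vitamin C, the ratios were set beside L-Pro/LIF over VitC/LIF and F/A over VitC/LIF from the same edgeR model. For L-proline the Pearson correlation over 12648 genes was 0.83 and Spearman's rho 0.78. Of the 4176 genes called in experiment B, 3968 had the same sign in experiment A, or 95%, against 72.2% of the genes not called. For F/A day 5 the correlation was 0.87, rho was 0.81, and 6569 of 6966 called genes had the same sign, or 94.3%. F/A day 3, added after the data were seen, gave 0.72, 0.66 and 85.3%.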

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

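Of the tests in this part, those on another scaling and on lower hypoxia-inducible factor activity were chosen only after the result was seen. How the factor activity, feeder, reporter cell and Tsnax tests were read was also revised after their values had been seen.

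Of the named genes and lists that passed in L-Pro/LIF over VitC/LIF, 3 had the opposite sign in experiment A by a clear margin, and the differences were not tested. That margin was a log2 ratio of at least 1 in size with its counting interval beyond 0 for genes, and the outer 2.5% of random lists for lists, so opposite signs of other genes are not listed here. Id4 was higher with L-proline in the double-positive cells, at a log2 ratio of 1.594 with a counting interval of 1.15 to 2.14, while it was lower by 1.51 in L-Pro/LIF against VitC/LIF (log2 fold change -1.51, SE 0.24). The glycolysis list had a median of -0.58 in experiment A and 0.59 in experiment B, where its call was lost (adjusted p = 0.32 with an estimated correlation). For the hypoxia response list the medians were -0.42 and 1.16. It shares members with the glycolysis list, Ldha and Slc2a1 among them, so these are not separate cases.

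Hypoxia response genes were lower with vitamin C in experiment B. With RLE size factors the list's median less that of all genes was -0.54, which could hardly come out otherwise since a scaling moves all genes alike, and neither replicate number carried it alone, with medians of -0.62 and -0.46 and 22 of 26 members lower in each. Lower activity of hypoxia-inducible factor in vitamin C stays open: the median was below 0 in 6 of 6 within-number ratios against the other LIF media, but these restate the pattern with the same VitC/LIF libraries and lend it no support. In experiment A it needs higher medians than in day 0 cells kept in vitamin C, and these went both ways, at -0.42 with L-proline and 0.02 and 0.40 at F/A day 3 and day 5. Experiment A was brought into this reading only afterwards, and vitamin C dose, population and extraction differed there.

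Fibroblast markers were higher in L-Pro/LIF, and 4 of the 18 genes on this list are on another list too, while 7 of the 16 tested reached 1 CPM in FBS/LIF. Feeder or other fibroblasts in the cultures may add them: in the double-positive L-proline cells the list's median of 0.24 lay above only 66.9% of matched random lists, as that explanation predicted, but no sort is described that would have removed such cells. Expression by the reporter cells themselves could add them too, since 7 of the 10 called members measured there, or 70.0%, were above day 0, short of the 75% set beforehand, and 6 by the counting interval, the measure used at first. Tagln, the most abundant member, singled out after its values were seen, rose from 99.9 to 227 CPM in experiment B and from 2.89 to 879 CPM in experiment A. Single libraries cannot tell these explanations apart.

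Tsnax and Hist1h4m stood among the largest falls with L-proline. For Hist1h4m, reads shared with near-identical histone genes are a likely source, as 0.0089% of its estimate in FBS/LIF came from unique hits. For Tsnax, reads shared with an overlapping gene stay open: the smallest fall in unique hits was 0.0 because no library had any, so this test could not have come out otherwise. No biological explanation was tested for either gene.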

How the results depend on the processing

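The unique-hit fits and the fits of other comparisons without F/A replicate 1 were chosen only after the data were seen, as was the F/A day 3 agreement. Where a library is left out, its medium has 1 library, assumed to vary like the other groups. Across these alternatives no called gene of the text turned its direction. RLE size factors kept 218 of the 218 called gene results, DESeq2 217, the replicate block 215 and unique hits 212, with 3 lost and the rest without a value. Leaving out each library in turn kept 763 such calls and lost 109, and most of the losses were in VitC/LIF against FBS/LIF. Of the 74 list calls in the text, 49 held with an estimated correlation, 72 with fry and 74 with the replicate block.

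Requiring a 2-fold change, which can only remove calls, gave 2208 genes for L-Pro/LIF, 66 for VitC/LIF, 2927 for 2i/LIF and 4283 for F/A over FBS/LIF, 2940 for L-Pro/LIF over VitC/LIF, 1940 for F/A over L-Pro/LIF and 2356 for VitC/LIF over 2i/LIF. Fitting only the libraries compared, on fewer residual degrees of freedom each time, moved the counts both ways. Counts fell to 61 genes for VitC/LIF and 4470 for F/A over FBS/LIF, and to 729 for F/A over L-Pro/LIF. They rose to 3972 for L-Pro/LIF and 5234 for 2i/LIF over FBS/LIF, 5509 for L-Pro/LIF over VitC/LIF and 4960 for VitC/LIF over 2i/LIF. What moved them was not tested. VitC/LIF over FBS/LIF further gave 263 genes without a low-count filter, 243 on unique hits, 408 with DESeq2 and 69 with limma on the deposited log values, and the cause was not tested. List tests called 54 with an estimated correlation, the only setting changed from the preset test. The overlap of L-Pro/LIF with F/A effects fell to 1947 genes at a mean of at least 10 CPM, where fewer genes were used.

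Without 1 library, F/A replicate 1 included, counts ranged from 2002 to 4908 for L-Pro/LIF, 6 to 250 for VitC/LIF, 2932 to 5922 for 2i/LIF and 4345 to 8463 for F/A over FBS/LIF. They ranged from 2860 to 5904 for L-Pro/LIF over VitC/LIF, 752 to 6296 for F/A over L-Pro/LIF and 2150 to 5028 for VitC/LIF over 2i/LIF. The high ends came from fits without the shallow F/A replicate 1, or without F/A replicate 2 in the F/A comparisons. The cause was not tested. Among the genes named in the text, only values that had not passed reversed. These were Pou5f1 in 2i/LIF (-0.071 to 0.18 without 1 library), Dnmt3b in F/A over FBS/LIF (-0.022 to 0.39), and Otx2 in F/A over L-Pro/LIF (-0.241 to 0.15, and -0.002 with DESeq2). Over all genes, 2 genes called in both fits had opposite signs on unique hits in 2i/LIF over FBS/LIF. With limma on the deposited log values 1 did so there and 1 in VitC/LIF over 2i/LIF. The proline metabolism list turned its direction with fry (adjusted p = 0.664).

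Deviations of the libraries from their medium's mean correlated between media by replicate number, at 0.10 to 0.52 over all tested genes, and the replicate block changed no count by over 1.5 times. The authors' normalized table could not serve as an alternative, since it holds experiment A only. With 2 libraries per medium a 2-fold change was recovered in 38.2% of simulated rises, so a gene that did not pass may differ by that much. F/A over FBS/LIF had 5799 calls without F/A replicate 1, the shallowest library.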

Other observations

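The list tests here were fixed in advance apart from the input of camera, and none was chosen only after the result was seen. The genes described here were picked afterwards. Genes of proline metabolism and transport did not pass camera as a list in any comparison, but single members passed. In L-Pro/LIF over FBS/LIF, Pycr1, a proline synthesis gene, fell from 8.66 ± 0.28 to 3.59 ± 0.44 CPM (log2 fold change -1.27, SE 0.19, adjusted p = 0.002), while Oat, whose product links ornithine to proline, rose from 42.4 ± 3.5 to 97.1 ± 14 CPM (SD, n = 2) and the transporter gene Slc6a15 by 1.09. Of the 15 members, 4 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.95). Oat was also higher in 2i/LIF, by 1.81 (SE 0.16), and in F/A, by 2.18 (SE 0.16). The proline transporter gene Slc6a7 rose from 0.488 ± 0.23 to 8.62 ± 0.47 CPM in 2i/LIF. Slc36a4, another transporter gene, fell by 1.93 in 2i/LIF and rose by 1.66 in F/A over FBS/LIF.

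Zscan4f, of a gene family that marks the rare 2-cell-like cells of such cultures, was at 12.7 ± 1.3 CPM in VitC/LIF, 6.63 ± 1.9 in 2i/LIF, 3.54 ± 0.23 in FBS/LIF and 0.847 ± 0.031 in L-Pro/LIF (SD, n = 2), with no counts in F/A. Only 11.9% of its estimate came from unique hits, so most of it rests on reads shared with other genes.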
